A study of Drosophila melanogaster with 18 samples.

How the data were processed

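Polyadenylated RNA was sequenced from wing imaginal discs of Drosophila melanogaster larvae at the end of the third instar, the stage at which they wander off the food. Per the labels, a heat shock at 37 °C for 30 min induced overlapping clones of cells, the transgene was kept silent at 18 °C, and animals were moved to 28 °C either 48 h or 78 h before dissection. The transgene encoded a dominant negative Tip60 or wild type Tip60, and a control arm was also sequenced. Each of the 18 libraries held 40 discs and was made directional. There were 6 groups of 3 libraries, 1 for each arm and duration.

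The deposited tables hold counts per FlyBase gene identifier, 1 table for each duration. Per the submitters' processing notes, the genome build was BDGP6 and featureCounts, FastQC, limma and edgeR 3.13.4 were used. The aligner, the strand setting of the counting, the annotation release and the treatment of reads that map to several places are not given in the sources used here. The values were whole numbers whose totals differed between libraries, from 65277725 to 105716567. Both tables list 17559 genes. Symbols and BDGP6 coordinates came from release 115 of the Ensembl annotation, matched by identifier for 17253 genes. The other 306 identifiers held between 5.69% and 6.01% of the counts of a library, were tested, and carry no name.

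The tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. For each duration the 9 libraries were fitted together with the group as the only term. Genes passed filterByExpr with its minimum of 10 counts, libraries were scaled by the trimmed mean of M values (TMM), and the edgeR quasi-likelihood test was run two-sided. Adjusted p is the Benjamini-Hochberg value over all genes tested in a comparison, and a gene is called at an adjusted p under 0.05 with no minimum fold. The common biological coefficient of variation was 0.181 at 48 h and 0.192 at 78 h. CPM values, counts per 1e6 library counts, were computed with the TMM factors, and errors beside them are standard deviations over 3 libraries. The SE of a log2 fold change is its size divided by the square root of the F statistic.

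The comparisons were Tip60 dominant negative against Tip60 wild type at each duration, each transgene against the control at each duration, and the difference of the first comparison between durations. That difference was tested as an interaction over all 18 libraries. Genes called in the same direction at both durations were counted against the number that independent calls would give, with a one-sided Fisher's exact test. Genes are not independent replicates, and its p describes the table of genes only.

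Altogether 23 gene lists were used, 17 for biological processes and 6 for other tissues. Of 628 entries, 593 matched a symbol of the annotation. Some well known members, wg, ap, Dl, vas and nos among them, were not matched and are not in the lists as tested. Lists with at least 5 tested members were tested with camera of limma at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 23 lists. The lists were NuA4 complex, S phase, mitosis, cell cycle regulators, apoptosis, DNA repair, JNK and regeneration, detoxification, heat shock chaperones, innate immunity, wing patterning, Hippo pathway, ecdysone and timing, neuronal, germline, Hox and Polycomb, ribosome biogenesis, hemocyte, fat body, muscle and myoblast, trachea, salivary gland and male markers. For each list, members were also adjusted over the list alone.

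Genes named in the text followed a rule. For each of the main comparisons it took Tip60, E2f1, CycE, stg, dap, Rbf and rpr, then the 5 highest and 5 lowest log2 fold changes among called genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups. It then took up to 2 members of each biology list with the smallest adjusted p among called ones, and the 2 members of each tissue list with the highest mean CPM. For comparisons with the control it took Tip60 and the 3 highest and 3 lowest log2 fold changes. Genes outside the rule are stated to be chosen after their values were seen. The groups, comparisons, tests, gene lists, rule for named genes and alternative settings were set before the data were examined, except where an alternative is stated to be chosen later.

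Replicate numbers were tested for pairing through correlations, across genes, between the residuals of libraries with the same number. Between the dominant negative and wild type libraries at 78 h these were 0.29, 0.35 and 0.32, and each library matched its own number best. At 48 h they were 0.01, 9.43e-04 and 0.25, and only number 3 matched best. Between wild type and control at 48 h they were 0.22, 0.06 and 0.22, and between Tip60dn and control 0.11, 0.03 and 0.07, with each library matching its own number best. At 78 h they were 0.07, -0.02 and 0.01, and -0.04, -0.10 and -0.07. Numbers were read as pairs where every correlation was over 0.1, which held between the dominant negative and wild type at 78 h. A fit with the number as a paired block term was run as an alternative, and its value stands beside a 78 h result where the call differs.

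Alternatives were DESeq2 size factors in edgeR, no low-count filter, DESeq2, limma-voom, a replicate block, only the 6 libraries compared, a minimum absolute log2 fold change of 1, and leaving out each library in turn. The pipeline was also tested on simulated data with the depth and spread of these libraries. There 48 to 50 genes were changed at each fold, or 100 for the interaction, and genes varied independently. That is far fewer changed genes than the real comparisons of Tip60dn with Tip60wt called. At 48 h the pipeline recovered 18.8% of genes changed 1.25-fold, 56.0% of those changed 1.5-fold, 56.0% of those changed 2-fold and 87.5% of those changed 4-fold, with 7 false calls (6.1% of calls). At 78 h these shares were 22.4%, 54.2%, 79.6% and 80.0%, with 10 false calls (7.9% of calls). The interaction test recovered 60.0% at 2-fold and 76.0% at 4-fold, with 5 false calls (3.5% of calls).

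The p-values measure only the spread between libraries. The labels describe separate pools of 40 discs and say nothing on independent cultures or crosses. Reads are not independent molecules, and counting intervals at 95% confidence cover counting error only.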

Results

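The data were gene counts of 18 libraries of wing discs, 3 in each of 6 groups: control, Tip60 wild type and Tip60 dominant negative (Tip60dn) after 48 h or 78 h of transgene expression. Tip60 is the acetyltransferase of the NuA4 chromatin complex, and the series asks which transcripts differ between discs with the dominant negative and discs with the wild type protein. At 48 h the libraries held 65277725 to 102795844 counts, and at 78 h 72693686 to 105716567. The most abundant transcript in every library was mt:lrRNA, with 2.40% to 3.06% of counts. In a principal component analysis the first component held 37.7% of the variance at 48 h and 41.9% at 78 h, and it set the Tip60dn libraries apart from the other 6 of their duration. All means below are over 3 libraries, and CPM values carry their standard deviation.

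Tip60 counts set both transgenes apart from the control, but both carry Tip60 sequence, so the counts cannot check which transgene a library holds. Tip60 (FBgn0026080, chromosome X, 4114800 to 4117487) stood at 33.6 ± 2.57 CPM in the 48 h control, 1625 ± 208 CPM with the wild type transgene and 3050 ± 466 CPM with the dominant negative. The Tip60dn level at 48 h was above the wild type level by 0.91 log2 (SE 0.12, adjusted p = 6.62e-04). At 78 h the means were 38.8 ± 5.84, 1579 ± 528 and 2083 ± 400 CPM, and the log2 difference of 0.40 (SE 0.24) did not pass the test, with an adjusted p of 0.223. With replicate numbers as a paired block it was 0.43, with an adjusted p of 0.0285, and without Tip60wt 78 h replicate 1 it was 0.15, without Tip60wt 78 h replicate 3 0.61 and without Tip60dn 78 h replicate 3 0.27. Counts of the transgene and of the endogenous gene cannot be separated here, and 21.0% of the Tip60 exons lie opposite tyf on the other strand. At 48 h the comparison of dominant negative with wild type also holds this difference in Tip60 level.

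**Figure D1:**
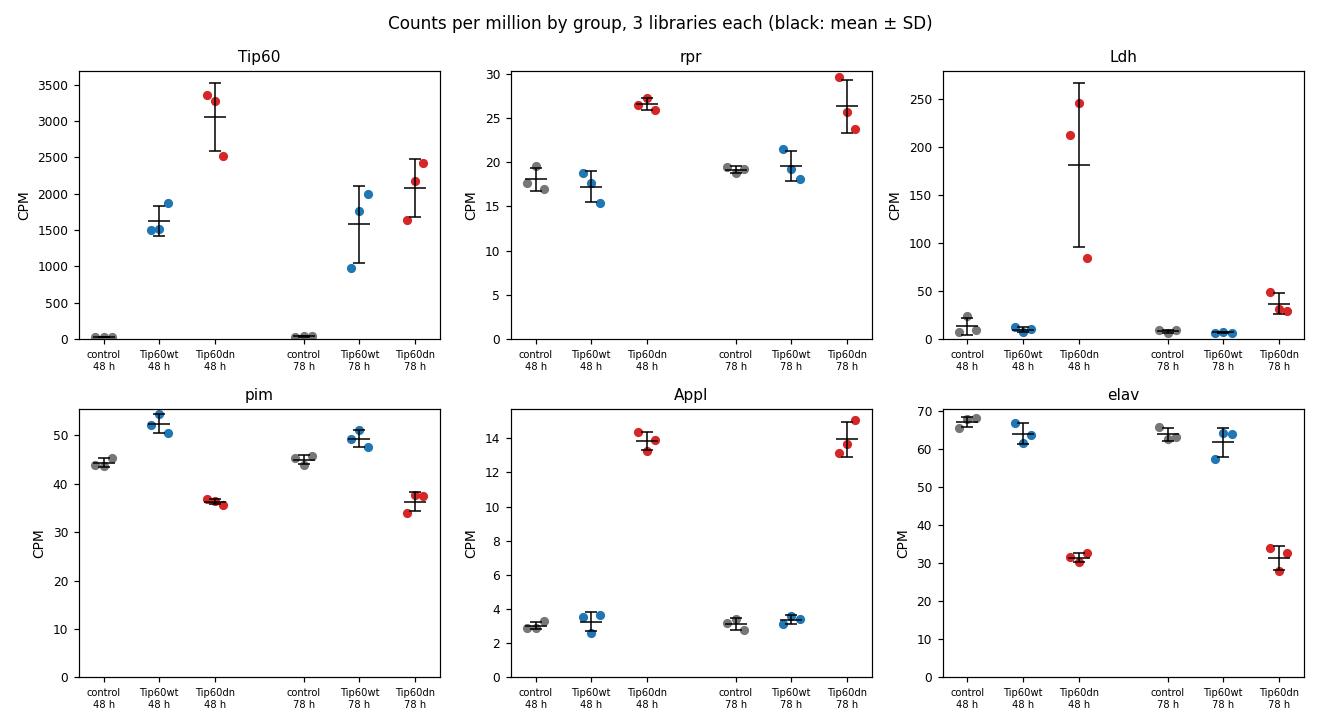
CPM of Tip60, rpr, Ldh, pim, Appl and elav in each group; points are libraries, black marks the mean and SD of 3 libraries, and each vertical axis starts at 0. At both durations the Tip60dn libraries lay above all others for rpr, Ldh and Appl and below all others for pim and elav.

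After 48 h, 25 of 45 mitosis genes were lower in discs with the dominant negative than with wild type Tip60, and 9 of 26 JNK and regeneration genes, 15 of 35 neuronal genes and 11 of 14 hemocyte genes were higher. With an estimated correlation the hemocyte list still passed (adjusted p = 0.0452), and the mitosis, JNK and neuronal lists did not (adjusted p = 0.511, 0.511 and 0.0885). The securin gene pim (FBgn0003087, chromosome 2L) fell from 52.4 ± 1.95 to 36.3 ± 0.586 CPM, while the TNF ligand gene egr (FBgn0033483, 2R) rose from 11.2 ± 0.688 to 20.2 ± 1.66 CPM. Appl (FBgn0000108, X), which encodes an amyloid precursor-like protein of neurons, rose from 3.27 ± 0.560 to 13.8 ± 0.534 CPM. Ldh (FBgn0001258, 3L), lactate dehydrogenase, rose from 10.0 ± 2.69 to 181 ± 85.4 CPM. Of 10693 genes tested, 3818 were called, 1924 higher and 1894 lower, with a median absolute log2 fold change of 0.32. At least a doubling or halving was seen in 771 of them, 664 higher and 107 lower. The 3 libraries of the groups did not overlap for 5314 genes, or 49.7% of those tested, against the 10% that chance gives, and 3774 called genes were among them.

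Cell cycle genes at 48 h moved mainly downward. Of 45 mitosis genes 25 fell and 0 rose, and adjusted over the list alone 27 fell (camera adjusted p = 1.23e-06, and adjusted p = 0.511 with an estimated correlation). Examples were pim, which fell by 0.53 log2 (SE 0.04, adjusted p = 3.67e-05), and borr, a subunit of the chromosomal passenger complex, which fell by 0.47 (SE 0.04, adjusted p = 8.35e-05). Among 25 cell cycle regulators 9 fell and 3 rose, and adjusted over the list alone 13 fell and 3 rose (camera adjusted p = 0.0234, and adjusted p = 0.435 with an estimated correlation). Cdk4, the partner of cyclin D, fell by 0.45 (SE 0.04, adjusted p = 8.86e-05), and Dp, the partner of E2F proteins, fell by 0.39 (SE 0.04, adjusted p = 2.85e-04). E2f1, the activating E2F, rose by 0.18 (SE 0.04, adjusted p = 0.0124), a call lost without Tip60wt 48 h replicate 3 (adjusted p = 0.0599). CycE, which drives entry into S phase, fell by 0.24 (SE 0.06, adjusted p = 0.0119). The Cdc25 phosphatase gene stg (log2 fold change 0.07, SE 0.09, adjusted p = 0.591), the Cdk inhibitor gene dap (-0.16, SE 0.06, adjusted p = 0.0649) and the retinoblastoma homolog Rbf (-0.08, SE 0.05, adjusted p = 0.265) did not pass the test, and dap passed it without Tip60wt 48 h replicate 3 (adjusted p = 0.0455) and in DESeq2 (0.0271). Of 33 S phase genes 12 fell and 3 rose, and adjusted over the list alone 13 fell and 3 rose, but the list did not pass (camera adjusted p = 0.0645). Gnf1, the large subunit of replication factor C, fell by 0.27 (SE 0.04, adjusted p = 1.89e-03). Psf3, a GINS subunit, rose by 0.34 (SE 0.06, adjusted p = 1.93e-03), with 34.9% of its exons opposite CG17841, so its counts are uncertain.

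Ribosome biogenesis genes also moved downward at 48 h: 13 of 27 fell and 4 rose, or 17 and 4 adjusted over the list alone (camera adjusted p = 0.0262, and adjusted p = 0.609 with an estimated correlation). Among all 2157 genes with a mean of 100 CPM or more, 739 fell and 327 rose at 48 h. No list was set against genes of like expression. The nucleolar gene Non2 fell by 0.32 (SE 0.04, adjusted p = 7.38e-04), while Nnp-1 rose by 0.47 (SE 0.08, adjusted p = 2.21e-03).

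In the JNK and regeneration list at 48 h 9 of 26 genes rose and 1 fell, and adjusted over the list alone 10 rose and 1 fell (camera adjusted p = 0.0069, and adjusted p = 0.511 with an estimated correlation). The JAK/STAT ligand gene upd1 rose by 0.86 log2 (SE 0.10, adjusted p = 3.15e-04), and Irbp18, a C/EBP-family factor, rose by 0.52 (SE 0.07, adjusted p = 7.05e-04). Of 20 apoptosis genes 8 rose and 3 fell, or 8 and 4 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0683). The killer gene rpr rose by 0.62 (SE 0.08, adjusted p = 5.10e-04), egr by 0.85 (SE 0.08, adjusted p = 1.08e-04) and the TNF receptor gene wgn by 0.42 (SE 0.04, adjusted p = 9.32e-05). Diap1, which blocks caspases and stands on the Hippo list as well, rose by 0.95 (SE 0.11, adjusted p = 2.82e-04). On that Hippo list 6 of 15 genes rose and 3 fell, 6 and 4 adjusted over the list alone (camera adjusted p = 0.151), and dlp, a glypican, rose by 0.52 (SE 0.06, adjusted p = 2.73e-04).

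The neuronal list was called higher at 48 h, with 15 of 35 genes up and 4 down, 16 and 4 adjusted over the list alone (camera adjusted p = 3.12e-04, and adjusted p = 0.0885 with an estimated correlation). Its members did not move one way: Appl rose by 2.08 log2 (SE 0.13, adjusted p = 1.54e-05), while elav, an RNA-binding protein of neurons, fell by 1.02 (SE 0.05, adjusted p = 4.91e-06). The elav gene shares 27.9% of its exons with lncRNA:enrr on the same strand. In the germline list 9 of 24 genes rose and 5 fell, 10 and 5 adjusted over the list alone (camera adjusted p = 0.0489, and adjusted p = 0.289 with an estimated correlation). Its call was lost without Tip60dn 48 h replicate 2 (adjusted p = 0.0856), Tip60dn 48 h replicate 3 (0.0889) or Tip60wt 48 h replicate 2 (0.0757). The piRNA pathway genes qin and spn-E rose by 1.27 (SE 0.09, adjusted p = 2.01e-05) and 0.96 (SE 0.08, adjusted p = 6.41e-05).

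Markers of blood cells rose with these groups. Of 14 hemocyte genes 11 rose and 0 fell at 48 h, 11 also adjusted over the list alone, with a median log2 fold change of 1.52 (camera adjusted p = 7.11e-13, and adjusted p = 0.0452 with an estimated correlation). Col4a1, a collagen IV chain, rose from 179 ± 23.2 to 292 ± 57.6 CPM (adjusted p = 6.12e-03), and Ppn, papilin, stood at 1093 ± 162 and 1077 ± 121 CPM (adjusted p = 0.933). The control discs held at least 10 CPM of 7 hemocyte genes as well. In the fat body list 4 of 10 genes fell and 0 rose, 6 and 0 adjusted over the list alone (camera adjusted p = 0.0952). GNBP3, a recognition protein for fungi, fell from 278 ± 9.87 to 231 ± 5.92 CPM (adjusted p = 1.21e-03). Fbp1, a receptor of the fat body, stood at 1197 CPM in Tip60wt 48 h replicate 2 against 111 and 5.12 CPM in the other 2 libraries, and its log2 fold change of -4.50 became -1.60 without that library (adjusted p = 0.0451 and 0.290). Its call was also lost without Tip60dn 48 h replicate 1 (adjusted p = 0.120), 2 (0.118) or 3 (0.116), in limma-voom (0.398) and with only the 6 libraries compared (0.0534).

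The remaining lists did not pass at 48 h. In the NuA4 list 3 of 17 genes rose and 4 fell, 5 and 4 adjusted over the list alone (camera adjusted p = 0.593), and Nipped-A, the scaffold subunit, rose by 0.42 log2 (SE 0.05, adjusted p = 3.98e-04). The list holds Tip60, the gene of the transgene, which is one of the 3 that rose. Of 34 DNA repair genes 10 rose and 4 fell, the same numbers adjusted over the list alone (0.235). The double-strand break gene nbs rose by 0.45 (SE 0.06, adjusted p = 6.24e-04), and the checkpoint clamp gene Hus1-like fell by 0.65 (SE 0.10, adjusted p = 1.11e-03), with 19.7% of its exons shared with ctrip on the same strand. Of 28 detoxification genes 9 fell and 1 rose, also adjusted over the list alone (0.0886). The glutathione transferases GstT1 and GstE5 fell by 0.42 (SE 0.04, adjusted p = 8.86e-05) and 1.02 (SE 0.14, adjusted p = 7.48e-04). Heat shock chaperones split into 3 up and 3 down of 22, 3 and 2 adjusted over the list alone (0.334). Hsp70Bb rose by 1.24 (SE 0.13, adjusted p = 1.75e-04), in a family of near-identical copies whose reads may not be told apart. Hsp67Ba fell by 0.79 (SE 0.10, adjusted p = 4.75e-04), with 75.9% of its exons opposite asRNA:CR43481. Of 16 immune genes 7 rose and 0 fell, also adjusted over the list alone (0.132). Dif, an NF-kappaB factor, rose from 4.91 ± 1.54 to 26.8 ± 10.4 CPM (adjusted p = 9.07e-03), and AttB, an antibacterial peptide gene with a close paralog in AttA, stood at 0.814 ± 0.133 against 0.276 ± 0.0870 CPM (adjusted p = 3.84e-03). Between dominant negative and control at 48 h, 1 of 16 immune genes rose and 0 fell, and 0 rose adjusted over the list alone (camera adjusted p = 0.940).

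Of 50 wing patterning genes 10 rose and 1 fell at 48 h, 7 and 0 adjusted over the list alone (camera adjusted p = 0.0777). The EGF receptor ligand gene vn rose by 0.37 log2 (SE 0.04, adjusted p = 3.82e-04) and the BMP ligand gene dpp by 0.36 (SE 0.05, adjusted p = 7.13e-04). In the ecdysone and timing list 5 of 28 rose and 4 fell, also adjusted over the list alone (0.523). Ldh rose by 4.18 (SE 0.53, adjusted p = 5.07e-04), and usp, the partner of the ecdysone receptor, fell by 0.46 (SE 0.06, adjusted p = 3.82e-04). Of 20 Hox and Polycomb genes 2 rose and 5 fell, also adjusted over the list alone (0.160). The trithorax group genes ash1 and brm fell by 0.37 (SE 0.06, adjusted p = 1.25e-03) and 0.28 (SE 0.05, adjusted p = 2.74e-03). Muscle and myoblast genes gave 3 up and 0 down of 23 (0.0624), trachea 3 and 0 of 9 (0.1025), salivary gland 1 and 0 of 8 (0.978) and male markers 1 and 0 of 5 (0.0624). Adjusted over the list alone these 4 lists gave 3, 5, 1 and 1 higher and 0 lower. Zasp52, a sarcomere protein, rose from 247 ± 13.8 to 320 ± 4.83 CPM (adjusted p = 1.11e-03), Gasp, a chitin-binding protein, from 132 ± 11.2 to 208 ± 6.05 CPM (4.82e-04) and the salivary gland factor gene sage from 8.92 ± 0.678 to 16.4 ± 2.86 CPM (1.55e-03). Tm1, verm, Sgs7, lncRNA:roX1 and msl-2 did not pass the test at 48 h, with adjusted p of 0.232, 0.258, 0.164, 0.228 and 0.0809. Sgs7 passed without Tip60dn 48 h replicate 3 (adjusted p = 0.0356) and msl-2 without Tip60wt 48 h replicate 1 (0.0460).

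The highest folds at 48 h were in genes near 0 CPM in wild type discs. TwdlC, a cuticle protein gene, reached 5.08 ± 0.599 CPM against 0.013 ± 0.023, from 1159 and 4 counts, a ratio of 337.5 with a counting interval of 131.4 to 1240.6 (adjusted p = 7.75e-05). Next came lncRNA:CR44316 (8.81 ± 1.51 against 0.049 ± 0.052 CPM, adjusted p = 4.38e-05), CG9377 (5.72 ± 2.10 against 0.045 ± 0.043, 1.99e-04), mthl8, a receptor of the methuselah family (31.9 ± 4.57 against 0.235 ± 0.322, 1.53e-04), and CG8620 (15.8 ± 21.8 against 0.092 ± 0.056, 4.57e-03, lost in limma-voom at 0.184). The CG8620 mean rests on Tip60dn 48 h replicate 2, at 40.96 CPM against 3.91 and 2.62 CPM in the other 2 libraries, and its log2 fold change of 7.36 became 5.10 without that library (adjusted p = 0.0093). The lowest were mfr, a ferlin gene, at 0.067 ± 0.059 CPM against 123 ± 52.3 and the cation channel gene TrpA1 at 0.082 ± 0.096 against 69.9 ± 31.0. The axonemal gene Tektin-C stood at 0.514 ± 0.140 against 40.1 ± 7.24 CPM and CG7900 at 0.113 ± 0.036 against 11.4 ± 1.12. Adjusted p of these 4 genes lay between 4.91e-06 and 1.24e-05. In the control these 4 genes were as low as with the dominant negative, at 0.142 ± 0.105, 0.099 ± 0.034, 0.447 ± 0.190 and 0.117 ± 0.044 CPM. CG14332 (0.034 ± 0.059 against 19.9 ± 18.5 CPM, adjusted p = 0.0489) lost its call in limma-voom (0.575), without Tip60dn 48 h replicate 1 (0.140), 2 (0.147) or 3 (0.122), and without Tip60wt 48 h replicate 1 (0.0946) or 2 (0.0753).

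**Figure D2:**
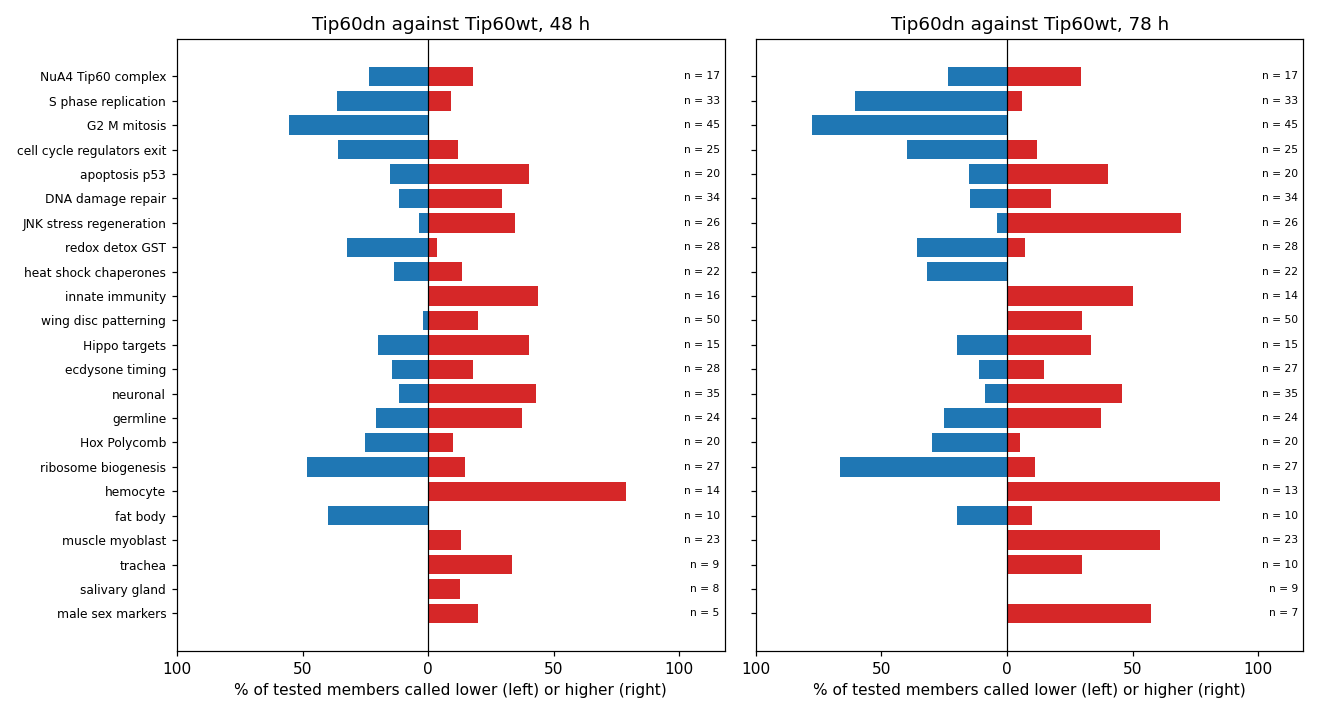
Share of the tested members of each gene list called higher (right, red) or lower (left, blue) in Tip60dn than in Tip60wt discs, in percent, at 48 h and 78 h; n is the number of members tested. Of 45 mitosis genes 25 fell at 48 h and 35 at 78 h, and 0 rose at either duration.

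After 78 h, 35 of 45 mitosis genes and 20 of 33 S phase genes were lower with the dominant negative, and 18 of 26 JNK and regeneration genes, 16 of 35 neuronal, 11 of 13 hemocyte and 14 of 23 muscle and myoblast genes were higher. With an estimated correlation none of these 6 lists passed (adjusted p = 0.318, 0.410, 0.0740, 0.0740, 0.318 and 0.318). Klp67A (FBgn0004379, 3L), a mitotic kinesin, fell from 88.7 ± 2.92 to 66.0 ± 3.05 CPM and pim from 49.3 ± 1.75 to 36.3 ± 2.01 CPM. Gadd45 (FBgn0033153, 2R), a stress-response gene, rose from 19.7 ± 4.29 to 49.1 ± 5.82 CPM, and Ldh from 7.13 ± 0.763 to 36.9 ± 10.9 CPM. Of 10598 genes tested, 3900 were called, 1869 higher and 2031 lower, with a median absolute log2 fold change of 0.30. A 2-fold change or more was seen in 736, of which 653 were higher and 83 lower. The libraries of the groups did not overlap for 5067 genes, or 47.8%, against the 10% that chance gives, and 3808 called genes were among them.

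Of 45 mitosis genes 35 fell and 0 rose at 78 h, 39 and 0 adjusted over the list alone (camera adjusted p = 1.37e-11, and adjusted p = 0.318 with an estimated correlation). Klp67A fell by 0.43 log2 (SE 0.04, adjusted p = 1.36e-04) and pim by 0.44 (SE 0.05, adjusted p = 2.19e-04). Of 33 S phase genes 20 fell and 2 rose, 22 and 2 adjusted over the list alone (camera adjusted p = 7.84e-05, and adjusted p = 0.410 with an estimated correlation). Cdc6, which licenses replication origins, fell by 0.42 (SE 0.05, adjusted p = 1.93e-04) and Gnf1 by 0.27 (SE 0.03, adjusted p = 4.34e-04). Of 25 cell cycle regulators 10 fell and 3 rose, 13 and 3 adjusted over the list alone (camera adjusted p = 0.0157, and adjusted p = 0.318 with an estimated correlation). Cdk4 fell by 0.38 (SE 0.04, adjusted p = 1.75e-04), and trbl, a pseudokinase that slows mitosis, rose by 0.42 (SE 0.05, adjusted p = 3.54e-04). E2f1 rose by 0.20 (SE 0.05, adjusted p = 9.45e-03) and CycE fell by 0.19 (SE 0.04, adjusted p = 9.09e-03). The gene dap fell by 0.21 (SE 0.05, adjusted p = 0.0152), a call lost without Tip60wt 78 h replicate 2 (0.0563). Rbf fell by 0.13 (SE 0.04, adjusted p = 0.0378), lost without Tip60dn 78 h replicate 1 (0.0841) or 3 (0.111), without Tip60wt 78 h replicate 2 (0.130) or 3 (0.0809), without control 78 h replicate 1 (0.0502), and with only the 6 libraries compared (0.0762). The gene stg did not pass (log2 fold change -0.08, SE 0.07, adjusted p = 0.441). Of 27 ribosome biogenesis genes 18 fell and 3 rose, 21 and 3 adjusted over the list alone (camera adjusted p = 8.51e-05, and adjusted p = 0.401 with an estimated correlation). Non2 and Nopp140 fell by 0.32 (SE 0.04, adjusted p = 7.11e-04) and 0.20 (SE 0.03, adjusted p = 1.64e-03).

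In the JNK and regeneration list 18 of 26 genes rose and 1 fell at 78 h, 18 and 2 adjusted over the list alone (camera adjusted p = 2.73e-05, and adjusted p = 0.0740 with an estimated correlation). Gadd45 rose by 1.31 log2 (SE 0.14, adjusted p = 1.92e-04) and upd1 by 0.87 (SE 0.10, adjusted p = 2.47e-04). Of 50 wing patterning genes 15 rose and 0 fell, 14 and 0 adjusted over the list alone (camera adjusted p = 5.07e-04, and adjusted p = 0.488 with an estimated correlation). The T-box gene Doc2 rose by 0.35 (SE 0.04, adjusted p = 4.42e-04) and vn by 0.36 (SE 0.05, adjusted p = 1.07e-03). Of 14 immune genes 7 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.0057, and adjusted p = 0.318 with an estimated correlation), and the list was lost with no low-count filter (0.122). Dif rose by 1.83 (SE 0.17, adjusted p = 9.99e-05). AttA stood at 0.191 ± 0.038 against 0.009 ± 0.015 CPM (adjusted p = 3.82e-03), and its log2 fold change of 4.37 became 7.07 without Tip60wt 78 h replicate 3.

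Among 28 detoxification genes 10 fell and 2 rose at 78 h, also adjusted over the list alone (camera adjusted p = 0.0141, and adjusted p = 0.318 with an estimated correlation). GstE1 fell from 23.1 ± 1.19 to 9.16 ± 0.484 CPM (adjusted p = 8.25e-06) and GstE8 from 6.51 ± 1.11 to 1.74 ± 0.417 CPM (1.61e-04), while the control held 13.1 ± 1.25 and 2.66 ± 0.106 CPM. Of 22 heat shock chaperones 7 fell and 0 rose, 4 and 0 adjusted over the list alone (camera adjusted p = 0.0352, and adjusted p = 0.401 with an estimated correlation). Its call was lost without Tip60dn 78 h replicate 1 (0.135) or Tip60wt 78 h replicate 3 (0.0621). Between dominant negative and control at 78 h neither list passed (camera adjusted p = 0.534 for detoxification and 0.536 for heat shock chaperones). Hsp26, a small chaperone, fell from 277 ± 24.1 to 147 ± 30.8 CPM (adjusted p = 1.61e-03), with 127 ± 18.3 CPM in the control. Hsp67Ba fell by 0.59 log2 (SE 0.08, adjusted p = 6.12e-04). Hsp68 fell from 78.3 ± 50.4 to 8.97 ± 3.97 CPM (adjusted p = 0.0368), but with the paired block its adjusted p was 0.0539, in limma-voom 0.0550, and it passed in none of the fits that left out a Tip60dn library (replicate 1 0.0967, 2 0.109, 3 0.0744) or a Tip60wt library (replicate 1 0.0948, 2 0.0535, 3 0.0512).

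In the neuronal list 16 of 35 genes rose and 3 fell at 78 h, 18 and 3 adjusted over the list alone (camera adjusted p = 7.22e-05, and adjusted p = 0.0740 with an estimated correlation). The synaptic vesicle gene unc-13 rose by 1.08 log2 (SE 0.03, adjusted p = 3.35e-07), with 25.2% of its exons opposite asRNA:CR43425, and Appl rose by 2.04 (SE 0.11, adjusted p = 4.78e-06). Of 13 hemocyte genes 11 rose and 0 fell, 12 and 0 adjusted over the list alone, with a median log2 fold change of 1.35 (camera adjusted p = 2.73e-05, and adjusted p = 0.318 with an estimated correlation). Col4a1 rose from 178 ± 18.2 to 270 ± 64.0 CPM (adjusted p = 0.0155), lost without Tip60dn 78 h replicate 2 (0.0564) or 3 (0.0631) or Tip60wt 78 h replicate 2 (0.0506), and Ppn stood at 995 ± 154 and 1165 ± 65.5 CPM (0.134). Tip60dn 78 h replicate 1 held fewer blood cell transcripts than its group: Hml, a hemocyte gene chosen after its values were seen, stood at 60.8 CPM there against 177 and 183. Of 23 muscle and myoblast genes 14 rose and 0 fell, 17 and 0 adjusted over the list alone (camera adjusted p = 4.67e-04, and adjusted p = 0.318 with an estimated correlation). Zasp52 rose from 242 ± 17.3 to 312 ± 19.7 CPM (adjusted p = 2.88e-03), and Tm1, tropomyosin, stood at 739 ± 9.71 and 721 ± 23.2 CPM (0.458).

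The other lists did not pass at 78 h. Of 20 apoptosis genes 8 rose and 3 fell, 9 and 3 adjusted over the list alone (camera adjusted p = 0.0940, and 0.0441 with the paired block). The gene rpr rose by 0.43 log2 (SE 0.09, adjusted p = 4.83e-03) and the signalling adaptor Traf4 by 0.55 (SE 0.06, adjusted p = 1.68e-04), with 26.8% of its exons opposite lncRNA:CR45363. The caspase gene Strica fell by 1.48 (SE 0.13, adjusted p = 7.86e-05), with 12.1 ± 1.70 CPM in wild type discs, 4.34 ± 0.0800 in Tip60dn and 4.47 ± 0.651 in the control. NuA4 genes gave 5 up and 4 down of 17, 5 and 5 adjusted over the list alone (0.923). The subunit genes MRG15 and dom fell by 0.28 (SE 0.03, adjusted p = 1.71e-04) and rose by 0.26 (SE 0.04, adjusted p = 6.18e-04). DNA repair gave 6 up and 5 down of 34, also adjusted over the list alone (0.839), with Rif1, which restrains replication, down by 0.32 (-0.32, SE 0.06, adjusted p = 2.38e-03) and tefu, the ATM kinase, up by 0.23 (SE 0.04, adjusted p = 2.57e-03). The Hippo list gave 5 up and 3 down of 15, 6 and 3 adjusted over the list alone (0.0922), and dlp and the pathway activator kibra rose by 0.52 (SE 0.04, adjusted p = 2.97e-05) and 0.33 (SE 0.04, adjusted p = 1.97e-04). The ecdysone and timing list gave 4 up and 3 down of 27, 3 and 2 adjusted over the list alone (0.176). Ldh rose by 2.37 (SE 0.21, adjusted p = 7.30e-05) and the ecdysone-induced factor Eip74EF by 0.44 (SE 0.06, adjusted p = 9.95e-04).

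Germline genes gave 9 up and 6 down of 24 at 78 h, also adjusted over the list alone (camera adjusted p = 0.176). The piRNA gene fs(1)Yb rose from 0.918 ± 0.055 to 6.82 ± 0.892 CPM (adjusted p = 3.42e-06) and spn-E from 11.3 ± 0.379 to 20.6 ± 0.724 CPM (7.08e-06). Hox and Polycomb genes gave 1 up and 6 down of 20, 1 and 7 adjusted over the list alone (0.333), and the Polycomb group genes Scm and esc fell by 0.22 log2 (SE 0.04, adjusted p = 2.55e-03) and 0.35 (SE 0.06, adjusted p = 3.03e-03). Fat body gave 1 up and 2 down of 10 (0.7885), trachea 3 and 0 of 10 (0.176), salivary gland 0 and 0 of 9 (0.176), and male markers 4 and 0 of 7 (0.141, and 0.0441 with the paired block), each with the same numbers adjusted over the list alone. GNBP3 fell from 270 ± 9.99 to 237 ± 2.63 CPM (adjusted p = 3.44e-03) and Gasp rose from 140 ± 25.2 to 191 ± 6.16 CPM (8.96e-03). The dosage compensation genes lncRNA:roX1 and msl-2 rose by 0.50 (adjusted p = 0.0246) and 0.29 (0.0292). The roX1 call was lost without Tip60dn 78 h replicate 2 (0.0532) or 3 (0.0911) or Tip60wt 78 h replicate 1 (0.0613) or 3 (0.0801). The msl-2 call was lost without Tip60dn 78 h replicate 3 (0.110) or Tip60wt 78 h replicate 1 (0.0838) or 3 (0.0591). Fbp1, verm, Sgs3 and Sgs7 did not pass, with adjusted p of 0.961, 0.219, 0.258 and 0.407. Without Tip60dn 78 h replicate 1 verm passed (adjusted p = 0.0487), and without control 78 h replicate 1 Sgs3 passed (0.0416). Sgs3, a glue protein of salivary glands, stood at 836 CPM in that control library against 16.6 and 6.10 CPM in the other control libraries. The median, the mean and the direction of camera differed in sign for DNA repair, Hox and Polycomb, fat body, trachea and male markers at 78 h, none of which passed.

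The highest folds at 78 h were again in genes near 0 CPM in wild type discs. TwdlC stood at 5.78 ± 0.462 against 0.018 ± 0.022 CPM, mthl8 at 31.0 ± 7.02 against 0.117 ± 0.051, CG34109 at 5.80 ± 0.620 against 0.030 ± 0.036 and lncRNA:CR44316 at 5.05 ± 1.63 against 0.060 ± 0.038. The channel gene ppk13 stood at 10.5 ± 3.07 against 0.103 ± 0.074 CPM, with 16.1 ± 1.23 CPM in the control. The lowest were mfr (0.137 ± 0.034 against 98.9 ± 44.0 CPM), TrpA1 (0.116 ± 0.062 against 55.7 ± 24.8), CG7900 (0.116 ± 0.154 against 11.3 ± 1.21), Tektin-C (0.455 ± 0.119 against 46.8 ± 2.75) and Hsp68. Apart from Hsp68, adjusted p of these 9 genes lay between 1.52e-06 and 2.40e-04.

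Many of the same genes moved at both durations. The same fly lines were compared each time, so any fixed difference between the lines would recur as well. Of 10396 genes tested in both, 1279 were higher and 1470 lower at 48 h and at 78 h, 2749 together, where independent calls would give 337.6 and 369.0. The odds ratios were 28.7 and 49.7, with a log10 p of -686.7 and -899.4 in one-sided Fisher's exact tests. The log2 fold changes had a Pearson correlation of 0.72 and a Spearman correlation of 0.72 across genes, which are not independent replicates. Among the genes moving together were pim, Cdk4, upd1, Ldh, Appl and spn-E. Only CG3961 and Pka-R2, named after their values were seen, were called in opposite directions, with log2 fold changes of -0.27 and 0.34 for CG3961 and -0.15 and 0.15 for Pka-R2. The interaction test in edgeR called 0 of 11173 genes, with 623 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 12. Without Tip60dn 48 h replicate 3 it called 8 genes and without Tip60dn 78 h replicate 1 it called 1. With every library in edgeR, a change at 1 duration alone was therefore not shown to differ between durations for a single gene.

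**Figure D3:**
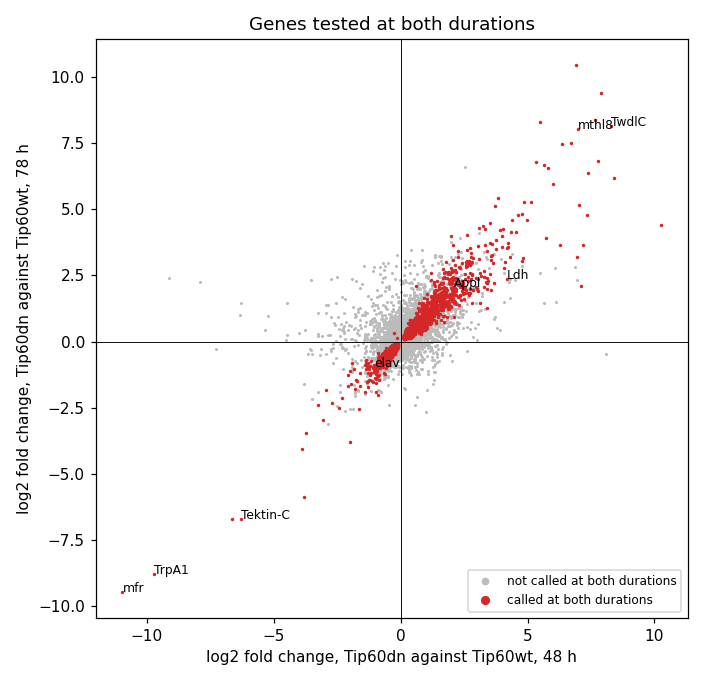
Log2 fold change of Tip60dn against Tip60wt at 48 h (horizontal) and 78 h (vertical) for each gene tested at both; red points were called at both durations. The 2749 genes called in the same direction lie in the lower left and upper right quadrants, and 2 called genes lie outside them.

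Wild type Tip60 discs differed from control discs in fewer genes. Tip60 itself was higher by 5.59 log2 at 48 h (SE 0.15, adjusted p = 7.12e-08) and 5.35 at 78 h (SE 0.29, adjusted p = 1.18e-05). At 48 h mfr (123 ± 52.3 against 0.142 ± 0.105 CPM) and TrpA1 (69.9 ± 31.0 against 0.099 ± 0.034 CPM) were higher with the transgene, and at 78 h they stood at 98.9 ± 44.0 and 55.7 ± 24.8 CPM against 0.281 ± 0.120 and 0.147 ± 0.108. These genes are neighbours on chromosome 3L, at 8905918 to 8912671 and 8894404 to 8905200. Dnaaf3, which helps to assemble dynein arms, had 0 counts in the 48 h control and 1677 in the wild type libraries, at least 559.8-fold higher against a floor of 3 counts over the group. CG7213 stood at 5.75 ± 1.43 against 0.010 ± 0.018 CPM at 78 h, from 1462 and 3 counts, a ratio of 496.3 with a counting interval of 169.5 to 2409.5. Its span overlaps that of Dscam4 on the other strand. With the dominant negative Dnaaf3 stood at 9.81 ± 0.96 CPM at 48 h and CG7213 at 7.33 ± 0.80 CPM at 78 h. For both genes the control thus stood apart from both transgene lines. Lower in wild type discs were ppk13 (0.232 ± 0.226 against 23.6 ± 2.99 CPM at 48 h, 0.103 ± 0.074 against 16.1 ± 1.23 at 78 h), CG33509 beside it (0.107 ± 0.099 against 10.95 ± 1.51, 0.044 ± 0.056 against 8.82 ± 0.792), CG1494 at 48 h (0.183 ± 0.075 against 9.11 ± 2.31) and the rootletin gene Root at 78 h (0.438 ± 0.085 against 33.3 ± 1.17). Adjusted p of these genes in this comparison lay between 5.22e-08 and 1.60e-03. Root was low with the dominant negative as well, at 0.67 ± 0.10 CPM at 78 h, so it too set the control apart.

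Of 10693 genes 382 were called between wild type and control at 48 h, 185 higher and 197 lower, and of 10598 at 78 h 431 were called, 222 higher and 209 lower. Groups did not overlap for 21.5% and 26.4% of genes, against the 10% that chance gives. With the preset correlation 13 of 23 lists passed at 48 h, 7 upward and 6 downward, and 7 at 78 h, 4 upward and 3 downward, and with an estimated correlation 0 passed at either duration (lowest adjusted p = 0.176 and 0.560). One of the upward lists at 48 h was NuA4 (camera adjusted p = 0.0027), which holds Tip60 itself. Tip60 was the only one of its 17 genes called. When 1 library at a time was left out, 3 of the 13 lists kept their call in every fit at 48 h, heat shock and detoxification upward and germline downward (camera adjusted p = 0.0027, and adjusted p = 0.246 with an estimated correlation), and 1 of the 7 at 78 h, heat shock. In these fits the direction reversed in 1 case at 48 h and 0 at 78 h. Of the other lists ranked downward at 48 h, mitosis (0.0066) and S phase (0.0167) were lost without Tip60wt replicate 1 (0.0985 for both) or 3 (0.0852 and 0.1730) or control replicate 2 (0.1077 and 0.1770). DNA repair (0.0027) was lost without control 48 h replicate 2 (0.0527), immune genes (0.0066) without Tip60wt 48 h replicate 3 (0.0503) and hemocyte genes (0.0041) without control 48 h replicate 3 (0.0586). At 78 h ribosome biogenesis (0.0128) was lost without Tip60wt replicate 2 (0.0725) or 3 (0.0984), and hemocyte genes (0.0106) without Tip60wt replicate 1 (0.1095). The salivary gland list (0.0195), with 0 of 9 genes called, was lost without control 78 h replicate 1 (0.1902), which held the high Sgs3 level, Tip60wt replicate 1 (0.0800), 2 (0.0529) or 3 (0.1300), or Tip60dn replicate 2 (0.0542) or 3 (0.0508). Of 22 heat shock chaperones 0 passed at 48 h and 2 at 78 h, 1 and 2 adjusted over the list alone. Camera ranked the list upward with adjusted p = 1.77e-05 at 48 h (adjusted p = 0.433 with an estimated correlation) and 2.75e-06 at 78 h (adjusted p = 0.560 with an estimated correlation). The counts of genes depended on single libraries. At 48 h 206 genes were called without Tip60wt replicate 1, 248 without Tip60wt replicate 3, 203 without control replicate 1 and 191 without control replicate 2, and DESeq2 called 718. At 78 h 981 were called without Tip60wt replicate 1, 210 without Tip60wt replicate 2, 237 without Tip60wt replicate 3, 203 without control replicate 1 and 209 without control replicate 3, and DESeq2 called 961.

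Between dominant negative and control discs 11 of 23 lists passed at 48 h and 14 at 78 h with the preset correlation, and 0 at either duration with an estimated correlation (lowest adjusted p = 0.151 and 0.0819). The NuA4 list, which holds Tip60 itself, was among the 11 at 48 h (camera adjusted p = 0.0101). Tip60 was higher by 6.50 log2 at 48 h (SE 0.16, adjusted p = 2.56e-08) and 5.75 at 78 h (SE 0.30, adjusted p = 3.05e-06). Mitosis genes were lower: 32 of 45 fell and 0 rose at 48 h, 34 and 0 adjusted over the list alone, and 38 fell and 0 rose at 78 h, 40 and 0 adjusted over the list alone. Camera gave adjusted p of 1.23e-09 and 5.83e-12, and adjusted p = 0.464 at 48 h and adjusted p = 0.326 at 78 h with an estimated correlation. Of 14 hemocyte genes 10 rose and 0 fell at 48 h, also adjusted over the list alone (camera adjusted p = 2.49e-07, and adjusted p = 0.151 with an estimated correlation). At 78 h 7 of 13 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.0156, and adjusted p = 0.540 with an estimated correlation), a call lost without Tip60dn 78 h replicate 2 (0.0624). In the JNK and regeneration list 8 of 26 rose and 1 fell at 48 h, also adjusted over the list alone (camera adjusted p = 0.0166, and adjusted p = 0.511 with an estimated correlation), lost without control 48 h replicate 1 (0.0675). At 78 h 18 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 4.29e-05, and adjusted p = 0.0819 with an estimated correlation). Lists called against wild type but not against control were germline at 48 h and detoxification, heat shock and immune genes at 78 h. Germline gave 6 up and 7 down of 24 (camera adjusted p = 0.736) and detoxification 7 and 10 of 28 (0.534). Heat shock gave 6 and 2 of 22 (0.536) and immune genes 5 and 0 of 14 (0.130). At 48 h Dnaaf3 had 0 counts in the control and 2288 with the dominant negative, at least 889.5-fold higher against the floor of 3 counts over the group. TwdlC stood at 5.08 ± 0.599 CPM at 48 h and 5.78 ± 0.462 CPM at 78 h, with 2 and 1 counts in the 3 control libraries, ratios of 675.9 (counting interval 186.7 to 5587.7) and 1497.0 (268.3 to 59167.2). The ratio of lncRNA:CR44316 at 48 h was 1196.1 (330.7 to 9883.1), and that of mthl8 at 78 h 3935.4 (1089.1 to 32501.8). At 78 h betaTry, a trypsin gene, had a ratio of 695.0 (192.0 to 5744.8), at 6.32 ± 10.4 CPM, with 18.4 CPM in Tip60dn 78 h replicate 2 against 0.161 and 0.417 CPM in the other 2 libraries. Adjusted p of these 5 genes lay between 7.57e-07 and 0.0208.

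Lower than control were Root (0.575 ± 0.135 against 34.4 ± 0.894 CPM at 48 h, 0.669 ± 0.102 against 33.3 ± 1.17 at 78 h) and CG15080 (1.94 ± 0.432 against 9.86 ± 1.99, 1.70 ± 0.281 against 9.27 ± 1.34). The maltase gene Mal-B2 stood at 3.11 ± 0.741 against 16.4 ± 2.54 CPM at 48 h, and CG5535 at 10.2 ± 3.98 against 39.1 ± 1.85 at 78 h. Adjusted p of these 4 genes lay between 2.27e-08 and 3.00e-04. At 48 h 4172 of 10693 genes were called, 2098 higher and 2074 lower, and groups did not overlap for 50.8%. At 78 h 4683 of 10598 were called, 2378 higher and 2305 lower, and groups did not overlap for 56.7%, against the 10% that chance gives. The control libraries serve both comparisons, so the counts are not independent of each other.

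**Figure D4:**
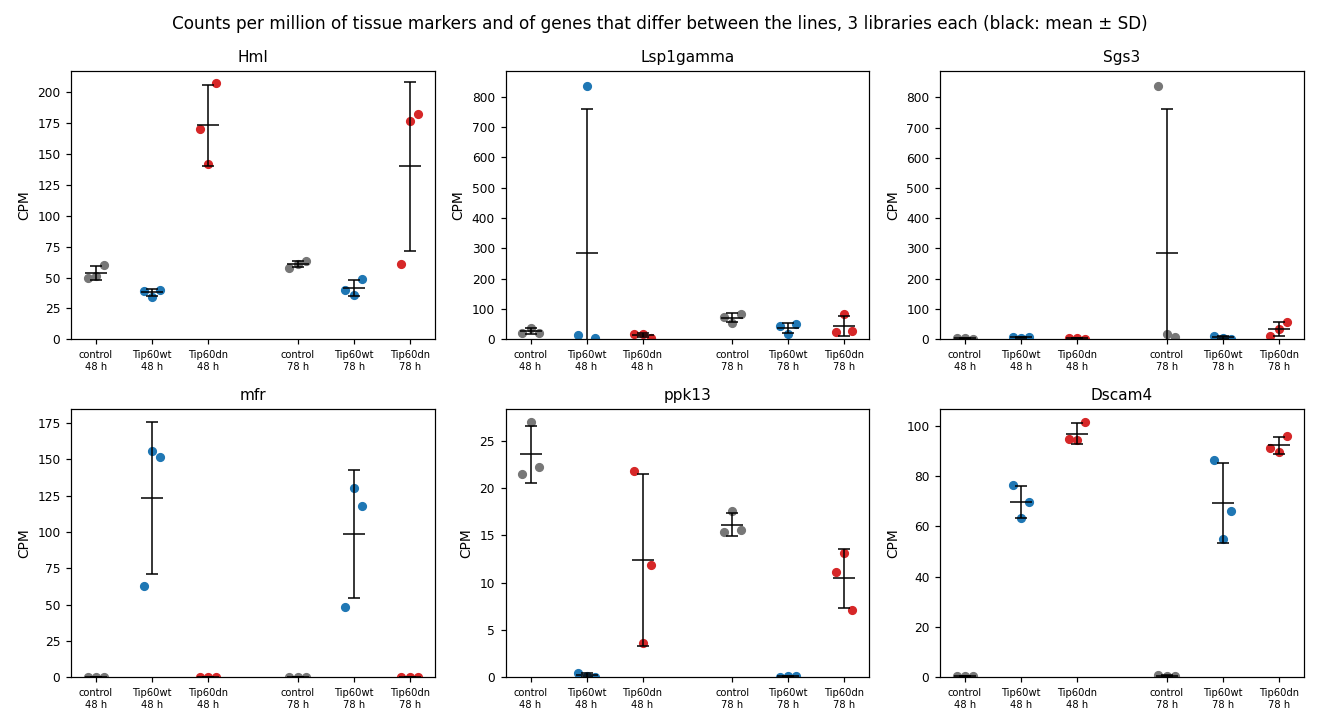
CPM of Hml, Lsp1gamma, Sgs3, mfr, ppk13 and Dscam4 in each group; points are libraries, black marks the mean and SD of 3 libraries, and each vertical axis starts at 0. Hml was lower in Tip60dn 78 h replicate 1 (60.8 CPM) than in the other 2 libraries of its group, Lsp1gamma reached 834 CPM in Tip60wt 48 h replicate 2 and Sgs3 reached 836 CPM in control 78 h replicate 1.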

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

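The interaction tests of gene lists and the regroupings were chosen after the results were seen. The difference between durations in the effect of the dominant negative, against wild type, was tested over 18 libraries with camera, and 10 lists differed with a preset correlation. With an estimated correlation 0 of them did, with adjusted p between 0.6169 and 0.6927, and edgeR called 0 genes of each list. Mean differences below are 78 h minus 48 h, in log2 units.

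The effect on S phase genes shifted downward from 48 h to 78 h (camera adjusted p = 0.0011, mean difference -0.08, 33 genes), as did that on mitosis genes (0.0162, -0.05, 45 genes), DNA repair genes (0.0034, -0.07, 34 genes) and ribosome biogenesis genes (6.88e-04, -0.08, 27 genes). Over 17 alternative settings the adjusted p ran from 5.36e-07 to 0.6646 for S phase, from 9.02e-05 to 0.7215 for mitosis, from 5.54e-04 to 0.6646 for DNA repair and from 4.68e-06 to 0.6646 for ribosome biogenesis. Without Tip60wt 78 h replicate 1 none of the 4 lists passed (adjusted p = 0.2889, 0.4986, 0.0830 and 0.2947). Without Tip60dn 48 h replicate 3 S phase (0.0643), mitosis (0.7215) and DNA repair (0.0659) did not pass. The mitosis list was also lost without Tip60wt 48 h replicate 1 (0.1123) or 3 (0.1765) and without Tip60dn 78 h replicate 2 (0.1156) or 3 (0.1333).

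The effect on wing patterning genes shifted upward (camera adjusted p = 0.0184, mean difference 0.06, 50 genes, range over settings 4.55e-04 to 0.9733), as did that on muscle and myoblast genes (0.0162, 0.11, 23 genes, 4.77e-04 to 0.6169). The wing list was lost without Tip60dn 48 h replicate 1 (0.2118), Tip60wt 48 h replicate 3 (0.1275), Tip60dn 78 h replicate 3 (0.9733) or Tip60wt 78 h replicate 1 (0.8969). The muscle list was lost without Tip60dn 48 h replicate 3 (0.0659), Tip60wt 48 h replicate 2 (0.1442) or Tip60dn 78 h replicate 2 (0.2505). Ecdysone and timing genes differed by 0.60 on average (0.0162, 28 genes, 0.0022 to 0.6169), a shift larger than their mean change at 48 h of -0.12. That list was lost without Tip60dn 48 h replicate 3 (0.2137), Tip60wt 48 h replicate 1 (0.0622), Tip60dn 78 h replicate 2 (0.0635) or Tip60wt 78 h replicate 1 (0.2889).

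Fat body genes differed by 2.42 (camera adjusted p = 0.0084, 11 genes, range over settings 1.05e-07 to 0.6646), and without Tip60wt 48 h replicate 2, where Fbp1 stood at 1197 CPM, the direction reversed (0.6417). The list was also lost without Tip60dn 48 h replicate 3 (0.1932), Tip60dn 78 h replicate 2 (0.0738) or Tip60wt 78 h replicate 2 (0.0657) or 3 (0.1303). Salivary gland genes differed by 1.31 (0.0220, 11 genes, 6.39e-10 to 0.6646), lost without Tip60dn 48 h replicate 3 (0.2154), Tip60wt 48 h replicate 2 (0.0641), Tip60dn 78 h replicate 2 (0.2059) or 3 (0.0672), or Tip60wt 78 h replicate 3 (0.1303). Male markers differed by -1.78 (0.0279, 9 genes, 0.0031 to 0.6169). They were lost with no low-count filter (0.1343), without Tip60dn 48 h replicate 1 (0.0907) or 2 (0.0519), Tip60wt 48 h replicate 2 (0.0845) or 3 (0.3444), Tip60dn 78 h replicate 1 (0.0983) or 2 (0.0635), and Tip60wt 78 h replicate 1 (0.3309) or 2 (0.0574).

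Regrouping the libraries gave as many lists often: of 100 drawn regroupings, the real one included, 28 gave 10 or more lists, with 16 in the highest other. Chance is thus not excluded for the number of lists that differ between durations. For genes the count was 0, which all 100 regroupings reached, and the highest other called 5784 genes. That draw exchanges the genotypes at 1 duration, and 7 others that called over 100 genes keep the genotypes whole at 1 duration and mix them at the other, so these 8 hold the effect of genotype. Among the 92 other draws 23 gave 10 or more lists. Of the 44 draws that part all 3 pairs of replicate numbers at 78 h, as the real grouping does, 17 gave 10 or more, with 16 in the highest other. The remaining 13 lists did not pass, and their adjusted p lay between 0.1009 and 0.9831.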

How the results depend on the processing

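The fits that joined 6 libraries with a replicate block, those of lists against control without 1 library, and the fit without control 78 h replicate 1 in the comparison of dominant negative with wild type, were chosen after the data were seen. Between Tip60dn and Tip60wt every alternative apart from the minimum fold kept the count of called genes within 1.5 times, and 0 shared calls changed sign. A gene called in 2 fits of largely the same libraries can hardly change sign. At 48 h 71.4% (6 libraries with the block) to 98.8% (DESeq2 size factors) of the main calls stayed called. At 78 h the range was 73.7% (without Tip60dn replicate 3) to 99.4% (DESeq2 size factors). A minimum absolute log2 fold change of 1 left 771 genes at 48 h and 736 at 78 h, 137 and 134 between wild type and control, 778 and 936 between Tip60dn and control, and 452 shared by both durations, by its own construction. DESeq2 called 718 and 961 genes between wild type and control, and 12 in the interaction, where edgeR called 0 genes (623 at an unadjusted p under 0.05); the cause was not tested.

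Leaving out 1 library at a time gave 2813 to 3456 genes at 48 h and 2949 to 3917 at 78 h between Tip60dn and Tip60wt, and 2202 to 2733 shared by both durations. Between Tip60dn and control it gave 3233 to 3876 at 48 h and 3610 to 4714 at 78 h. Between wild type and control it gave 191 (without control 48 h replicate 2) to 525 (without control 48 h replicate 3) and 203 (without control 78 h replicate 1) to 981 (without Tip60wt 78 h replicate 1). For the interaction the range was 0 to 8, with 8 without Tip60dn 48 h replicate 3 and 1 without Tip60dn 78 h replicate 1. The cause was not tested.

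Of the lists, 7 passed at 48 h and 12 at 78 h with the preset correlation, against 1 and 0 with an estimated correlation, which widens the test where members move together. By fry, which asks only whether a list's own genes move one way, 15 passed at 48 h and 18 at 78 h. The log2 difference of Tip60 at 78 h was 0.40, 0.43 with the paired block, which passed, and 0.45 with 6 libraries and the block, which passed as well. Without 1 library it ran from 0.15 to 0.61.

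For the named genes other than Tip60 at 48 h, 768 of 791 alternative values kept direction and call, and at 78 h 837 of 865. At 48 h the sign of stg reversed to -0.01 without Tip60wt replicate 3 (range -0.01 to 0.17), and that of Ppn reversed to 0.05 without Tip60dn replicate 1 and 0.06 without Tip60wt replicate 3 (range -0.14 to 0.06). At 78 h that of Fbp1 reversed to -0.43 without Tip60wt replicate 2 (range -0.43 to 0.56). None of these 3 genes passed the test there. When 1 library was left out, the adjusted p of the fat body list in the interaction ran from 1.05e-07 (without Tip60wt 48 h replicate 3) to 0.6417 (without Tip60wt 48 h replicate 2, direction reversed), and it was 0.6646 with an estimated correlation. At 48 h, where the numbers were not read as pairs, the replicate block ended the call of Fbp1 (0.2050, and 0.3051 with 6 libraries), and 6 libraries with the block that of the ribosome biogenesis list (0.0520). Depth limits genes near 0 CPM, where folds rest on few counts.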

Other observations

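The tests of explanations and the splits in this part were chosen after the results were seen, and the genes outside the naming rule after their values were seen.

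Splits of the 6 libraries of each comparison numbered 10, the real one included, too few for a share under 0.05. Between Tip60dn and Tip60wt the real split gave 3818 genes at 48 h and 3900 at 78 h, and the highest other 0 and 0, so 1 split of 10 reached the real count each time. Between wild type and control the real counts were 382 and 431 and the highest others 7 and 0, with 1 of 10 each. Between Tip60dn and control they were 4172 and 4683, and 0 and 0, again 1 of 10 each. Every other split mixes the genotypes, so an effect of genotype widens the spread within its groups and lowers its count. The low gene counts of those splits are therefore no measure of what chance alone gives. For gene lists at 48 h the real split gave 7, the highest other 12, and 6 of 10 splits gave as many. For lists at 78 h it gave 12, the highest other 10, and 1 of 10 gave as many. Replicate numbers pair the libraries at 78 h: among the 4 splits that part all 3 pairs, the real one gave 12 lists and 3900 genes and the others 10, 7 and 8 lists and 0 genes each. The other 6 splits part 1 pair each. For genes called alike at both durations, 1 of all 200 pairs of splits reached the real count of 2749, with 2 in the highest other. Each split other than the real one called 0 genes, so a pair that held one gave 0 in advance. The pair that gave 2 was the real split at both durations with the direction exchanged at 1 of them. This count therefore cannot decide whether chance made the overlap.

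The hemocyte list was higher with the dominant negative than with wild type at both durations, and with an estimated correlation it passed at 48 h (adjusted p = 0.0452) but not at 78 h (adjusted p = 0.318). A lower share of epithelium would raise the genes of 4 other tissues alike, if epithelium lacks their transcripts and carry-over is equal between genotypes. Neither condition was tested. At 48 h the hemocyte median lay above those of 4 lists by more than the larger SD. The gaps were 1.12 log2 for muscle and myoblast, 1.19 for trachea, 1.64 for salivary gland and 4.38 for fat body. The fat body gap became 1.66 (larger SD 1.39) without Tip60wt 48 h replicate 2. At 78 h the hemocyte median did so for 2 lists, trachea (1.21, SDs 0.63 and 0.90) and fat body (1.23, SD 0.82). The muscle gap of 0.93 lay below the SD of 0.96, and salivary gland genes had a median of 1.77. Without Tip60dn 78 h replicate 3 or Tip60wt 78 h replicate 1 the trachea list alone did so (1.13 and 1.08). Against control at 78 h the medians were 0.68 for hemocyte, 0.43 for muscle and myoblast, 0.42 for trachea, 0.06 for fat body and -2.99 for salivary gland. These gaps therefore do not decide whether the share of epithelium was lower. Of 6 Tip60dn libraries 6 stood above every wild type library of their duration, 3 of 3 above every control library at 48 h and 2 of 3 at 78 h, and the list was lower in wild type than in control (camera adjusted p = 0.0041, lost without control 48 h replicate 3 at 0.0586, and 0.0106, lost without Tip60wt 78 h replicate 1 at 0.1095, and adjusted p = 0.433 and 0.6205 with an estimated correlation). Carry-over at dissection that differs by genotype cannot be told apart from a genotype effect, since each genotype is its own set of discs; more blood cells on the disc may be a biological explanation.

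Of 35 neuronal genes 15 rose and 4 fell with the dominant negative at 48 h, and 16 rose and 3 fell at 78 h (adjusted p = 0.0885 and adjusted p = 0.0740 with an estimated correlation). RNA of nervous tissue is argued against, since Syn, VGlut, Gad1 and ChAT reached at most 0.25 CPM in Tip60dn while called members rose by a median of 9.92 CPM at 48 h and 9.17 at 78 h. RNA of the blood cells stays open: with the hemocyte level of each library in the 78 h model the mean log2 fold change of the called members was 1.22 (SD 1.09) against 1.28 (SD 0.98) without it, 7 of 16 stayed called and the list passed (camera adjusted p = 2.06e-04, and adjusted p = 0.218 with an estimated correlation), while hemocyte members went from 1.36 to -0.10. In this fit the fall of the hemocyte members was given in advance, since the added term was the mean level of their own list. That fit rests on Tip60dn 78 h replicate 1, which held few blood cell transcripts: without it the mean was 1.70 (SD 2.69), 0 of 16 stayed called as the median SE grew from 0.26 to 0.72, and the list was lost (0.1255). At 48 h the mean went from 1.29 (SD 1.01) to 1.44 (SD 2.08) and 0 of 15 stayed called, as the median SE grew from 0.14 to 0.79, so these lost calls speak neither for nor against blood cell RNA. A rise of these transcripts within disc cells is another candidate explanation, which was not tested.

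A set of 20 genes stood at least 2 log2 units apart in wild type Tip60 discs from both other lines at both durations, 9 higher and 11 lower. They formed 6 neighbour pairs within 50 kb, such as TrpA1 with mfr and ppk13 with CG33509, against at most 3 in a one-sided permutation test with 10000 random sets (p = 1.00e-04, the smallest these sets can give), which is consistent with differences between fly lines in background or insertion site. Testis RNA is argued against, since Mst87F, dj and betaTub85D reached at most 0.64 CPM while mfr and Tektin-C stood at 40.06 CPM or more. An effect of wild type Tip60 on them stays open. For the control line the same rule gave 13 genes, Dnaaf3, CG7213 and Root among them, with 3 pairs against at most 3 in random sets (permutation p = 2.00e-04). For Tip60dn it gave 85 genes, 81 of them higher, with 12 pairs against a random median of 4 and at most 13 (permutation p = 6.00e-04). Every comparison of genotypes here is also one between lines. Fixed line differences can therefore enter the called genes at both durations and their overlap, and their share was not tested.

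Among 2692 genes with a mean under 1 CPM at 48 h, 401 rose at least 2-fold and 44 fell with the dominant negative, against 32 and 26 between wild type and control. At 78 h 362 of 2599 rose and 34 fell, against 33 and 24. At 100 CPM or more 10 genes rose at least 2-fold and 1 fell at 48 h, and 8 rose and 1 fell at 78 h. Counted at any fold, 435 rose and 51 fell under 1 CPM at 48 h and 396 and 37 at 78 h, while at 100 CPM or more 327 rose and 739 fell at 48 h and 367 and 764 at 78 h. Direction thus followed expression level over all genes. The gene lists were set against all genes tested, so a list of mostly high or mostly low genes can share this trend. How far the list results do so was not tested. Of 603 genes annotated as ncRNA, a class apart from snoRNA and snRNA, 119 rose and 19 fell at 48 h, and of 562 at 78 h 107 rose and 18 fell. Over all genes 1924 of 10693 rose and 1894 fell at 48 h, and 1869 of 10598 rose and 2031 fell at 78 h. The share of ncRNA genes that rose was thus close to that of all genes, and only the share that fell was smaller. They were not set against genes of like expression. Of 142 snoRNA genes 1 rose and 2 fell at 48 h, and of 133 at 78 h 3 rose and 2 fell. Of 13 snRNA genes 1 rose and 0 fell at 48 h, and 3 rose and 0 fell at 78 h.

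Ilp8, a relaxin-like hormone released by damaged discs, rose from a mean of 0.256 to 5.08 ± 3.32 CPM at 48 h (adjusted p = 0.0117). At 78 h Ilp8 was also higher with the dominant negative, at 2.37 ± 1.78 CPM (adjusted p = 1.77e-03). Xrp1, a stress-response factor, rose from 471 ± 31.8 to 824 ± 73.5 CPM at 48 h (6.62e-04) and by 0.68 log2 at 78 h (SE 0.10, adjusted p = 7.47e-04). Snap25, a synaptic fusion protein, rose by 2.31 log2 at 48 h (adjusted p = 6.41e-05) and 2.80 at 78 h (1.66e-04).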
